A study of Mus musculus with 16 samples.

How the data were processed

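Splenic effector memory T cells of 4 female wild-type C57Bl6/J mice, 1 year and 1 month old, were sorted by how strongly they bound SNA, taken here as the sialic acid-binding lectin Sambucus nigra agglutinin. Per the labels' protocols, 100 SNA-high and 100 SNA-low cells per mouse were collected from the CD4 and from the CD8 effector memory gate, lysed at once, and turned into libraries with a low-input RNA kit. The titles place the 16 libraries in 4 groups of 4: CD4 SNA-high, CD4 SNA-low, CD8 SNA-high and CD8 SNA-low. The mice were separate animals, so the replicates of a group are biological, with each mouse contributing to every group.

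The values analysed were 2 tables of the authors' own comparisons, 1 for CD4 and 1 for CD8 cells. Each held a gene name, the authors' log2 fold change between the SNA gates and the authors' adjusted p-value as −log10, per the file headers. Trim Galore, DESeq2 and the mouse build mm39 were used by the authors, per the submitters' processing notes, which name no versions. The aligner, the counting tool, the annotation, any filter on low counts, the model formula and whether the replicate number entered it are not given in the sources used here. Neither the headers nor the labels say which SNA gate is the numerator of the fold change. Directions are therefore given as the positive or the negative side of the authors' deposited table, and no side is assigned to SNA-high or SNA-low cells. Every comparison of signs between the CD4 and CD8 tables assumes that both take the same gate as numerator.

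Values per library, standard errors, unadjusted p-values, mean counts and sequencing depth were not used here, so the depth behind each fold change is unknown and no SD of replicates can be printed. The CD4 table had 3441 entries, 5 of them without a gene name, leaving 3436 named genes. The CD8 table had 2859 entries, 3 without a name, leaving 2856. Unnamed entries were left out of every count and list, and entered only the number of tests behind the adjusted p-values. Genes past an adjusted p of 0.05 in the authors' values are referred to as called.

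The spread behind each fold change was bounded from the authors' own numbers. A step-up (Benjamini-Hochberg) adjusted p-value gives back the unadjusted p of a gene up to the ranks of the genes tied with it, taking the entries of the table as the tests made. The upper and lower bounds on p differed by a factor of at most 1.14 in CD4 and 1.17 in CD8. The upper bound was turned into a normal z statistic, and the log2 fold change divided by z gave an upper bound on its standard error. This assumes a Wald test, unshrunken fold changes and no further tests behind the adjustment, none of which the sources used here state. The median upper bound was 0.72 log2 units in CD4 and 0.66 in CD8, so at the median a log2 change of 1.41 in CD4 and 1.29 in CD8 lies at the edge of a 95% interval around 0. Genes with a fold change of exactly 0 have no bound.

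The CD4 and CD8 effects were compared gene by gene with a z test on the difference of the authors' log2 fold changes, dividing by the root of the summed squared standard error bounds, two-sided and Benjamini-Hochberg adjusted over 2851 genes. It treats the comparisons as independent, although the same 4 mice gave all cells. Genes called in both tables were counted by sign, with an exact two-sided binomial test and Fisher's exact test, and their number was set against the overlap of independent lists. Genes are not independent replicates in any of these tests.

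A set of 34 gene lists was fixed before the data were examined: sialylation and other glycan enzymes, lectins, sialic acid carriers, T cell states and lineages, cell programmes, and markers of other cell types. Within each list, called positive and negative members were counted, and the count was repeated with the authors' p-values adjusted over the list alone. For lists with at least 3 called members, Fisher's exact test (two-sided) compared positive with negative calls in the list and among the other called genes, Benjamini-Hochberg adjusted over 14 tests. The shift of all listed members against the other genes was tested with camera of limma 3.58.1 in R 4.3.3 on the z statistics, for lists with at least 3 members, at a preset inter-gene correlation of 0.01. That test, its repeats at a correlation of 0.1 and on ranks, and the standard error bounds were chosen after the data had been seen. A correlation estimated from libraries could not be used, since it needs values per library.

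Gene types and transcript sequences came from GENCODE M21, which describes an older mouse build (GRCm38) than the authors' build. It served for names, types and sequences only, and no coordinates are given. A type was found for 96.1% of named genes in CD4 and 96.4% in CD8. The coding gene closest to each listed pseudogene was the best match by blastn 2.17.0 on the sense strand. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

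The p-value recovery and the difference test were tested on simulated data before use. Camera was tested on simulated data too, but only after its run on the real values. The true p-value lay within its bounds for 100% of 3438 simulated CD4 genes and of 2856 simulated CD8 genes. Over 2851 simulated genes the difference test called 79 of 100 genes with a log2 difference of 4, 23 of 100 with a difference of 2, and 5 of 2651 without a difference. For a list of 30 among 2856 simulated CD8 genes, camera called 1% of 100 draws without a shift and 100% with a shift of 1 unit of z. These simulations check the computation only. They take the assumptions behind the bounds as true, and the camera draws had no correlation between genes, so neither is tested by them.

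Genes named were chosen by a rule fixed before the data were examined. Among called genes other than predicted genes and antigen receptor segments, it takes in each direction the 6 with the smallest adjusted p and the 4 with the largest fold change, up to 4 members of each list, and the 10 strongest genes called in both tables. It adds Cd44, Cd4, Cd8a and Cd8b1 whatever their p. The largest fold changes were to be taken among genes with at least the median count, and without counts they were taken among all called genes. Antigen receptor segments were read as variable, diversity and joining segments, so constant region genes were kept. Outside this rule, Foxp3, Xcl1, St8sia4, Tcf7, Igkc, Cd74, Cd83, H2-DMa and, in CD4, Ccl3 were chosen after their values were seen, and Ctsw, Cd82, Mphosph6 and Glrx are named as genes past the difference test. St6gal1 and St6gal2, also in the rule, are not analysed here. Some genes that the rule names are counted with the others but not reported here.

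The alternatives were other thresholds on the authors' adjusted p, a minimum log2 change of 1, leaving out predicted genes and receptor segments, other sets of genes in the list test, and, added after the data had been seen, leaving out pseudogenes and the settings of the difference and list tests named above. Of the tests on explanations in the closing section, the bound for carried-over B cells was rewritten after its result had been seen, when further B cell genes were added to it; with Igkc alone the result had counted against such cells. Without values per library, no model was refitted, no replicate was left out and the libraries were not regrouped.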

Results

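RNA from small pools of splenic effector memory T cells was compared between cells that bound the lectin SNA strongly and cells that bound it weakly, separately in the CD4 and the CD8 lineage. The data comprise 16 libraries from 4 mice, with 4 libraries in each of the 4 groups and 100 sorted cells per library. The study's title places the work in the presentation of sialic acid-bearing glycans on T cells. The sequencing depth of the libraries is unknown here, and the fold changes and adjusted p-values are the authors' own. A positive or negative sign is given as the authors' deposited table has it, since the SNA gate used as numerator is not stated.

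In CD4 effector memory T cells, genes of cytotoxic and chemokine-producing T cells lay on the positive side, and genes of regulatory T cells on the negative side. In the authors' deposited table the chemokine gene Ccl5 differed 118-fold (log2 fold change 6.88, adjusted p = 5.21e-54), and Nkg7, a cytotoxic granule protein gene, 17.2-fold (log2 4.11, adjusted p = 2.87e-38). The granzyme gene Gzmk followed at 30.5-fold (log2 4.93, adjusted p = 1.51e-17) in the authors' deposited table. On the negative side of the authors' deposited table, the immunoglobulin heavy chain gene Ighm had a log2 fold change of −3.36 (adjusted p = 2.4e-11), the costimulatory receptor gene Tnfrsf4 −3.22 (adjusted p = 8.33e-07) and the decoy receptor gene Il1r2 −6.45 (adjusted p = 6.99e-06). Of 3436 named genes in the authors' deposited CD4 table, 46 were called (1.34%), 26 positive and 20 negative, with absolute log2 fold changes from 1.00 to 7.34.

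**Figure D1:**
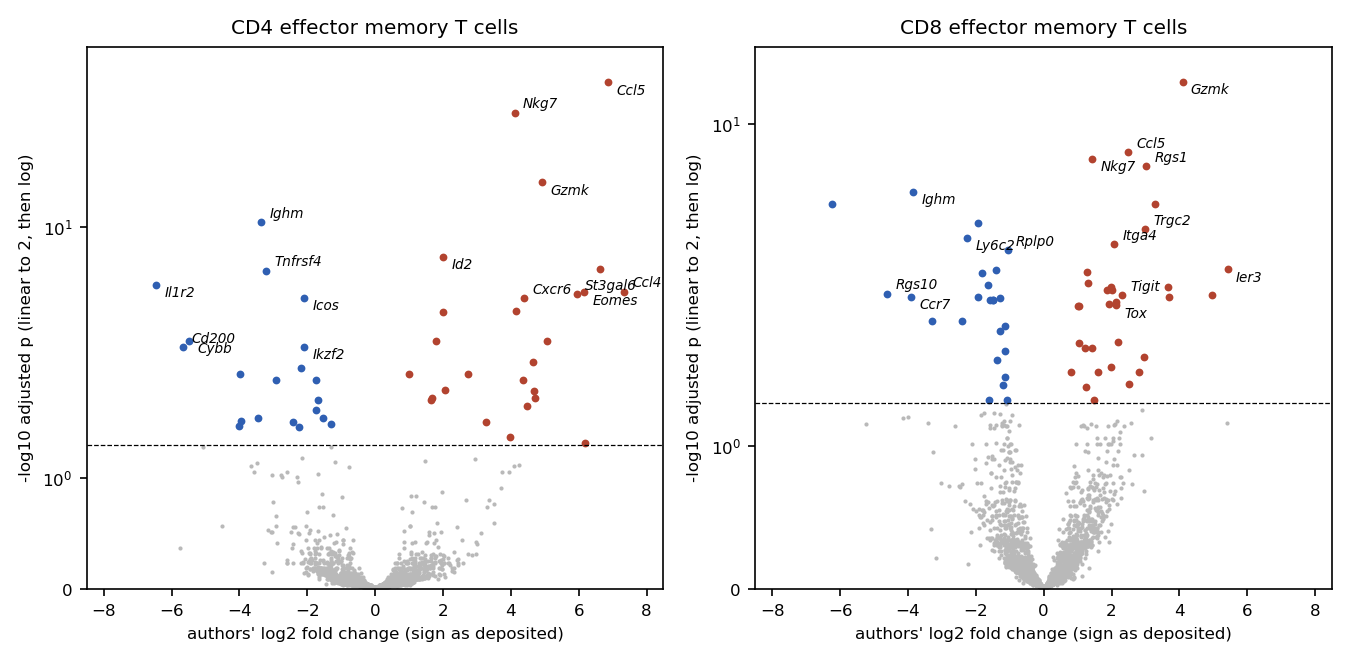
The authors' log2 fold change between the SNA gates (x axis, sign as deposited) against −log10 of their adjusted p (y axis, linear up to 2 and logarithmic above) for each named gene of CD4 (left) and CD8 (right) effector memory T cells. Points are genes, red and blue points are the positive and negative calls (26 and 20 in CD4, 34 and 25 in CD8), grey points are other genes, and the dashed line marks an adjusted p of 0.05.

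Among CD4 genes, those of the effector and cytotoxic list lay mainly on the positive side. Of its 30 listed members, 15 were called positive, 1 was called negative and 14 were not called, which differed from the signs of the other called genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0024). Adjusted over the list alone, 22 were positive and 1 negative. Besides Ccl5, Nkg7 and Gzmk, the authors' deposited table gave positive log2 fold changes for the chemokine genes Ccl4 (7.34), Ccl3 (4.70) and Xcl1 (4.69), and for Gzma (6.19) and the pore-forming protein gene Prf1 (4.36). It also gave 6.15 for Eomes, a transcription factor gene of cytotoxic and memory lymphocytes, and 2.01 for the transcriptional regulator gene Id2, while Fasl, the ligand of a death receptor, stood at 3.97 in the authors' deposited table. The negative member was the integrin gene Itgb1, with a log2 fold change of −2.43 in the authors' deposited table. Of 11 listed Th1 genes, 5 were called, all positive (among them Ccl5, Nkg7, Cxcr6 and Fasl; adjusted p = 0.119; 7 positive and 0 negative adjusted over the list alone), and 12 of the 17 genes on that list are also on the effector list. The chemokine receptor gene Cxcr6 had a log2 fold change of 4.39 in the authors' deposited table.

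Of 14 listed regulatory T cell genes, 6 were called in CD4 cells, all negative (Fisher's exact test, adjusted p = 0.0290). Adjusted over the list alone, 12 were negative and 1 positive. The called members were Tnfrsf4, the costimulator gene Icos (−2.09), Ikzf2, which encodes the transcription factor Helios (−2.10), Capg (−2.20), the ectoenzyme gene Nt5e (−2.92) and Nrp1 (−4.02), with log2 fold changes from the authors' deposited table. Foxp3, the lineage factor of these cells and a gene chosen after its values were seen, was not called (log2 −3.04, adjusted p = 0.0967 in the authors' deposited table). Of 14 follicular helper genes, 4 were called, all negative (adjusted p = 0.0788; 8 adjusted over the list alone). They were Icos, Cd200 (−5.65), Tnfsf8 (−3.98) and Slamf6 (−1.75), with log2 fold changes from the authors' deposited table. Among 17 age-associated genes, 7 were called positive and 3 called negative (adjusted p = 0.606; 7 and 5 adjusted over the list alone), and among 17 checkpoint genes 1 was called positive and 2 called negative (adjusted p = 0.667; 2 and 5 adjusted over the list alone).

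Of the CD4 genes that act on sialic acid itself, St3gal6, a sialyltransferase that adds sialic acid to galactose, was called at 61.3-fold (log2 5.94, adjusted p = 2.27e-05) on the positive side of the authors' deposited table. The other listed sialyltransferase gene, St8sia4, had a log2 fold change of 0.35 there (adjusted p = 0.950), and the 3 listed genes of sialic acid synthesis and removal and the 3 listed genes of other glycan enzymes were not called. The remaining sialyltransferases are not analysed here, and how St3gal6 bears on SNA binding, if at all, was not tested. Of 23 listed carriers of sialic acid, Itgb1 alone was called (1 negative adjusted over the list alone). The activation marker gene Cd44 (log2 −0.76, adjusted p = 0.830) was not called in the authors' deposited table, nor were Cd4 (−1.07, adjusted p = 0.840) and Cd8b1 (0.87, adjusted p = 0.935), and Cd8a was listed at 0. The other called genes under the rule were Ctla2a (4.16), Rgs1 (2.01) and the cytokine receptor gene Il7r (1.66) on the positive side of the authors' deposited table, and Cd200, Ly6a (−1.67), Ifi27l2a (−1.73) and the replication gene Mcm6 (−2.24) on its negative side.

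Markers of other cell types moved along with these groups. The 5 listed B cell markers were negative in CD4 (camera, adjusted p = 3.22e-08 and 3.23e-06 at a correlation of 0.1), with Ighm called and 4 negative adjusted over the list alone. The oxidase gene Cybb, used here as a myeloid marker and also expressed by B cells, had a log2 fold change of −5.49 (adjusted p = 0.0020) in the authors' deposited table. Of 6 listed NK cell markers, 4 were called, all positive (Fisher's exact test, adjusted p = 0.202; 5 adjusted over the list alone), and these were Nkg7, Eomes, Prf1 and Gzma, which T cells also express. Listed erythroid, platelet and stromal markers numbered 0, so those cell types are not analysed here.

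In CD8 effector memory T cells, cytotoxic and chemokine genes again lay on the positive side, while ribosomal protein genes lay on the negative side as a group. Gzmk differed 17.1-fold (log2 4.09, adjusted p = 2.41e-15) in the authors' deposited table, Ccl5 5.64-fold (log2 2.497, adjusted p = 1.67e-08) and Nkg7 2.71-fold (log2 1.44, adjusted p = 4.65e-08). On the negative side of the authors' deposited table stood Ighm (log2 −3.86, adjusted p = 3.39e-06) and the homing chemokine receptor gene Ccr7 (log2 −3.90, adjusted p = 0.0075). Of 2856 named genes in the authors' deposited CD8 table, 59 were called (2.07%), 34 positive and 25 negative, with absolute log2 fold changes of at least 0.81. Of the 25 negative calls, 16 were pseudogenes. Positive genes made up 57.6% of the CD8 calls, 79.1% without pseudogenes and 68.0% without predicted genes and receptor segments.

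The effector and cytotoxic list had 9 of 27 listed members called in CD8 cells, all positive (Fisher's exact test, adjusted p = 0.0339; 17 positive and 0 negative adjusted over the list alone). The other called genes in that test, 25 positive and 25 negative, include the 16 negative pseudogenes. It was not repeated without them, so its p-value may depend on them. The called members included Ccl3 (log2 4.96), Ccl4 (3.69), Prf1 (2.20) and Id2 (1.31) in the authors' deposited table. Of 16 age-associated genes, 6 were called, all positive (adjusted p = 0.0788; 9 positive and 1 negative adjusted over the list alone), and 8 of the 22 genes on that list are also on the effector list. Of 14 checkpoint genes, the inhibitory receptor gene Tigit (log2 2.32, adjusted p = 0.0069) and Tox, a transcription factor gene of exhausted T cells (2.14, adjusted p = 0.0103), were called positive in the authors' deposited table, and 5 were positive adjusted over the list alone. Immediate early genes were called positive in 4 of 22 listed cases (adjusted p = 0.202; 4 positive and 1 negative adjusted over the list alone). These were Ier3 (log2 5.43), Rgs1 (3.02), Klf6 (1.99) and the activation marker gene Cd69 (1.86) in the authors' deposited table.

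Naive and central memory genes were called negative in 4 of 14 listed CD8 cases (Fisher's exact test, adjusted p = 0.0788; 4 negative adjusted over the list alone). They included Ccr7, Ly6c1 (log2 −3.30) and Ly6c2 (−2.25) in the authors' deposited table, and the Ly6c genes are also expressed by memory CD8 T cells. Other members were not called, among them the transcription factor gene Tcf7 (−0.58, adjusted p = 0.667 in the authors' deposited table), chosen after its values were seen. The signalling regulator gene Rgs10, outside this list, had a log2 fold change of −4.62 (adjusted p = 0.0064) and the interferon-induced Ly6e one of −1.37 (adjusted p = 0.0248) in the authors' deposited table.

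Ribosomal protein genes were lower than other genes in the CD8 fold changes as a group. Of 81 listed members, 77 were negative, with a median log2 fold change of −0.48 (quartiles −0.68 and −0.28; camera, adjusted p = 1.61e-14 and 0.0012 at a correlation of 0.1). Only Rplp0 was called (log2 −1.06, adjusted p = 5.66e-04 in the authors' deposited table), and 7 were negative adjusted over the list alone. The 16 called pseudogenes were all closest in sequence to a ribosomal protein gene, among them Rpl13-ps3 (−1.41) and Rps19-ps6 (−1.81) in the authors' deposited table. Of 268 such pseudogenes in CD8, 256 were negative, with a median log2 fold change of −0.99. Their sequences were 98.6% identical to the closest coding gene at the median, so reads cannot be assigned with certainty to either copy and the pseudogene values are uncertain. The nuclear RNA Malat1 lay on the other side in CD8 (log2 1.04, adjusted p = 0.0103 in the authors' deposited table), as did the called immediate early genes. In CD4 the 82 listed ribosomal protein genes had a median log2 fold change of 0.23 (camera, adjusted p = 0.0039, and 0.356 at a correlation of 0.1), with 0 called.

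Other CD8 genes under the rule were the integrin gene Itga4 (log2 2.08), the T cell receptor complex gene Cd3g (0.81), the kinase gene Fyn (1.49), the inflammatory caspase gene Casp1 (2.13), Ctla2a (1.94) and the nuclear RNA Malat1 (1.04), all positive in the authors' deposited table. Itga4 was the only called member of 23 carriers of sialic acid, 5 being positive adjusted over the list alone (camera, adjusted p = 0.0046, and 0.112 at a correlation of 0.1). The 2 listed sialyltransferases were not called in CD8: St3gal6 had a log2 fold change of 0.41 (adjusted p = 0.789) and St8sia4 one of 0.85 (adjusted p = 0.706) in the authors' deposited table. Cd44 (0.94, adjusted p = 0.552), Cd8a (0.30, adjusted p = 0.749) and Cd8b1 (0.15, adjusted p = 0.875) were not called there, and Cd4 was listed at 0 in the authors' deposited table.

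The T cell receptor gamma chain constant genes Trgc2 (log2 2.99, adjusted p = 1.28e-04) and Trgc4 (2.95, adjusted p = 0.0237) were called positive in the authors' deposited CD8 table. Whether they come from gamma-delta T cells was not tested. The 5 listed B cell markers had a median log2 fold change of −3.33, with 4 negative and 1 positive (camera, adjusted p = 2.36e-04, 0.0022 at a correlation of 0.1 and 0.0671 on ranks at that correlation), with Ighm called and 2 called negative when adjusted over the list alone. Of 6 NK cell markers, Nkg7 and Prf1 were called positive, and 4 were positive adjusted over the list alone.

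**Figure D2:**
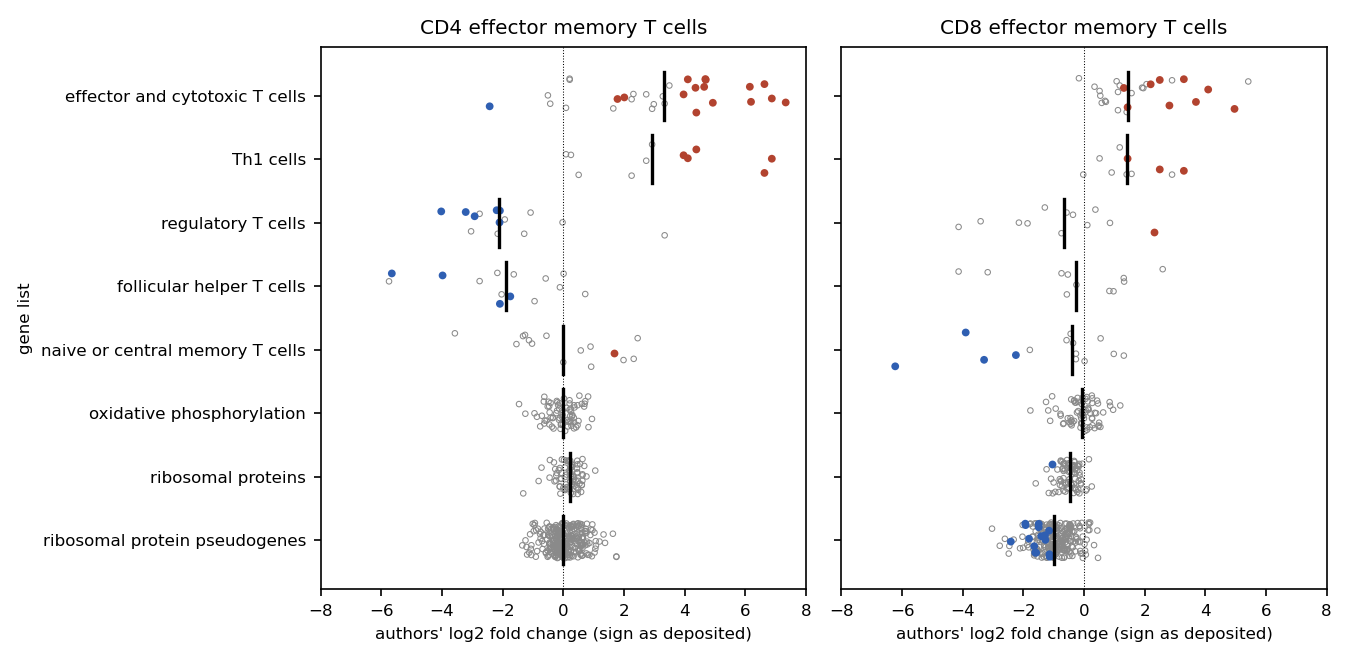
The authors' log2 fold change (x axis, sign as deposited) of each listed member of 8 gene groups (y axis) in CD4 (left) and CD8 (right) effector memory T cells. Each circle is a gene, filled red or blue where the authors' adjusted p was under 0.05 with a positive or negative sign, and black bars are medians, such as −0.48 for ribosomal proteins in CD8 and 0.23 in CD4.

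Whether the SNA gates separated the same genes in both lineages was addressed by comparing the tables. Both lineages shared 11 called genes, 10 of them positive in both, among which were Ccl5, Nkg7, Gzmk, Id2, Ccl4, Ccl3, Ctla2a, Rgs1 and Prf1, and Ighm was negative in both. Independent lists of these sizes would share 0.93 genes (exact hypergeometric p = 6.59e-10). That comparison takes the 2856 genes of both tables as all genes tested, which no source used here states. It also takes no account of the shared mice or of a spread estimate that both comparisons may share. All 11 shared genes had the same sign (exact binomial p = 9.77e-04, two-sided), while Fisher's exact test of sign against sign, with a single negative gene, gave p = 0.0909. Of 45 CD4 calls with a CD8 value, 38 had the same sign there (exact binomial p = 3.12e-06), 25 of the 26 positive and 13 of the 19 negative ones. Of 59 CD8 calls, 46 had the same sign in CD4 (exact binomial p = 1.92e-05), 28 of the 34 positive and 18 of the 25 negative ones. The 25 negative CD8 calls include 16 pseudogenes that are near copies of ribosomal protein genes and may share reads. The test on the CD8 calls counts each of them separately and was not repeated without them, so its p-value is uncertain. Across all 2856 genes of both tables, which are not independent replicates, Pearson's r of the log2 fold changes was 0.28 and Spearman's rho 0.13.

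**Figure D3:**
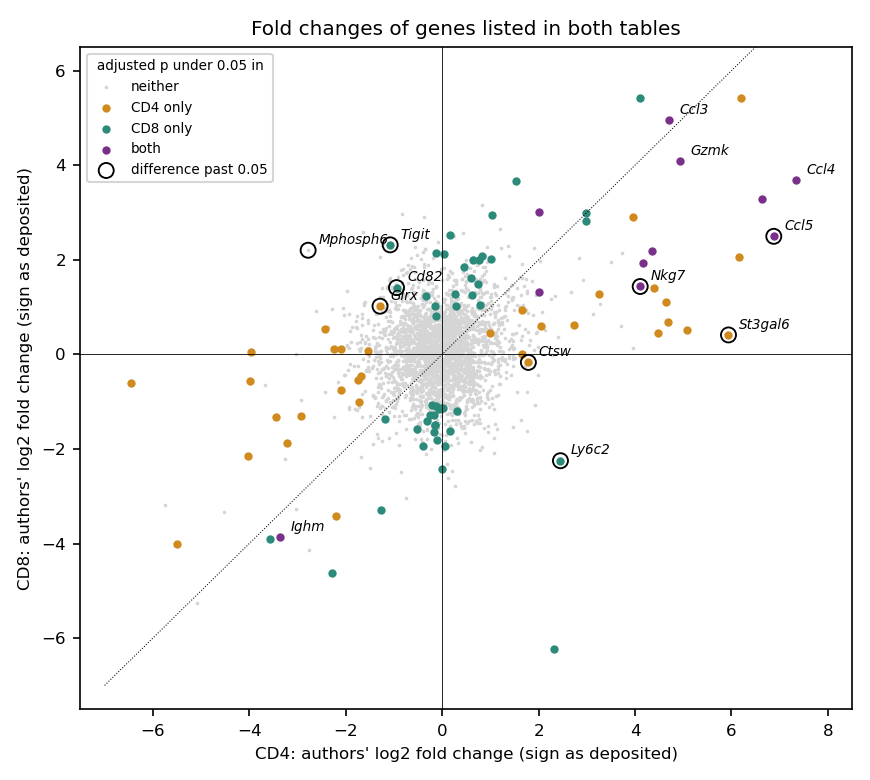
The authors' log2 fold change in CD4 (x axis) against that in CD8 (y axis) for genes listed in both tables, signs as deposited. Colours mark genes with an adjusted p under 0.05 in CD4 only, in CD8 only or in both (11 genes, all of the same sign), rings mark 9 genes whose difference passed its test, and the dotted line marks equal values.

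The size of the SNA-associated difference was not the same in both lineages for 10 genes (z test of the difference, Benjamini-Hochberg adjusted). Ccl5 was more positive in CD4 by a log2 difference of 4.38 (95% interval 3.27 to 5.49, adjusted p = 2.86e-11) and Nkg7 by 2.67 (1.94 to 3.41, adjusted p = 1.4e-09). St3gal6 differed by 5.53 (3.16 to 7.89, adjusted p = 0.0027). Tigit was more positive in CD8, with a CD4 minus CD8 difference of −3.39 (−4.85 to −1.94, adjusted p = 0.0027). Further genes past the threshold were Ctsw, Ly6c2, Cd82, Mphosph6 and Glrx, of which the last 3 were more positive in CD8. These intervals rest on standard error bounds derived here from the authors' values, and 276 of 2851 genes had an unadjusted p under 0.05.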

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

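Of the tests named in this part, those of transcript length and of reads shared with parent genes were set out before their results were seen, and the difference test between lineages was planned. The other tests of explanations, the list tests with camera and the standard error bounds were chosen after the data had been seen. Splits of the libraries into other groups were not counted, since that needs values per library.

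The difference between the CD4 and the CD8 effect of the SNA gates passed its own test for 10 genes, and the CD4 minus CD8 log2 differences of 9 of them follow. They were 4.38 for Ccl5, 2.67 for Nkg7, 5.53 for St3gal6, 4.70 for Ly6c2 and 1.958 for Ctsw. The differences were −3.39 for Tigit, −2.36 for Cd82, −4.98 for Mphosph6 and −2.31 for Glrx. Ly6c2 and Ctsw both lay near the threshold (adjusted p = 0.0462) and were lost when the statistic was divided by its robust SD of 1.07. Mphosph6 was not called in either table (adjusted p = 0.0967 in CD4 and 0.109 in CD8 in the authors' deposited table).

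As groups, 8 gene sets differed between the lineages in the shift of all members (camera at a correlation of 0.1). The adjusted p was 0.0037 for effector and cytotoxic genes, 6.99e-05 for Th1 genes and 4.37e-04 for NK cell markers, all more positive in CD4. These are not separate results, since 12 of the 17 Th1 genes and 6 of the 26 NK cell markers are also on the effector list. The adjusted p was 0.0298 for checkpoint genes, 0.0298 for regulatory T cell genes and 0.0134 for follicular helper genes, all more negative in CD4. For ribosomal protein genes it was 4.37e-04 and for their pseudogenes 2.27e-04, both more negative in CD8. On ranks at the same correlation, ribosomal protein genes and their pseudogenes alone stayed past 0.05 (adjusted p = 0.0015 for each), and the other 6 sets lay between 0.0938 and 0.133. The 2 sets are not separate results, as the pseudogenes were 98.6% identical to the closest coding gene at the median in CD8. Across 113 pseudogenes of other genes, the CD8 fold change followed that of the closest coding gene (Spearman's rho = 0.687). Whether a correlation of 0.1 covers such near copies was not tested, so the p-values of the pseudogene set are uncertain.

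Ribosomal protein genes and their pseudogenes lay on the negative side in CD8. A wrong library scaling would move other abundant genes alike, but oxidative phosphorylation genes had a median log2 fold change of −0.0545 (bootstrap 95% interval −0.12 to 0.084) against −0.48, and coding genes matched on transcript length had 0.113, with 0 of 10000 random sets as low, which argues against scaling and length as the cause. The pseudogenes may largely repeat the coding genes through shared reads, since across 113 pseudogenes of other genes the fold change followed that of the closest coding gene (Spearman's rho = 0.687, permutation p = 1e-05, the smallest the permutations can give), although 226 of 262 ribosomal pseudogenes lay below their parent, by a median of −0.42. More naive-like or central-memory-like cells on the negative side stay possible, as that list shifted the same way (adjusted p = 0.0157 at a correlation of 0.1, and 0.172 on ranks). A difference in RNA quality or cell handling also stays open, as Malat1 (log2 1.04 in the authors' deposited table) and immediate early genes (camera, adjusted p = 0.0416 at a correlation of 0.1, and 0.170 on ranks) lay on the other side. The RNA quality list that holds Malat1 did not shift in CD8, with 3 listed genes positive and 2 negative (camera, adjusted p = 0.147, and 0.243 at a correlation of 0.1). For RNA quality the point therefore rests on Malat1 alone. A difference that goes with SNA binding itself stays open too and was not tested.

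Ighm, an immunoglobulin gene, was negative in both lineages of sorted T cells. B cells carried over by the sort could bring it, and the median of the B cell genes Cd74, Cd83 and H2-DMa, chosen after their values were seen, was −4.53 in CD4 and −3.33 in CD8. Igkc, an abundant B cell transcript, did not follow, lying above Ighm by z = 2.63 in CD4 and 3.51 in CD8. Free RNA with Igkc in both gates would hide such a difference, so carried-over cells and another source of Ighm cannot be told apart here. Whether SNA binding by the T cells themselves goes with these transcripts was not tested.

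Cytotoxic genes were positive in CD4 cells. CD8 T cells carried over into the CD4 gate would bring Cd8a and Cd8b1 along with Nkg7, but Cd8b1 lay below Nkg7 by a log2 difference of −3.24 (z = −2.39). Cd8a was listed at 0 in CD4 cells, without a bound on its standard error. These values argue only weakly against such cells as the whole cause. The test set Cd8b1 against 1 of the strongest genes of the pattern, a pair picked after the data had been seen. NK cells, which the CD4 gate should remove, would bring the abundant NK cell genes Tyrobp and Fcer1g, but of these 0 were listed. Any filter on low counts is unknown, so their absence does not settle the question and NK cells remain possible. Carried-over NK cells and CD4 T cells with a cytotoxic programme cannot be told apart by these genes. A difference among CD4 T cells in SNA binding stays open as the biological explanation and was not tested.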

How the results depend on the processing

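Settings concerning pseudogenes, the difference test and camera were chosen after the data had been seen, and the others before the data were examined. At an adjusted p of 0.01 the called genes numbered 21 in CD4 (46 at 0.05) and 33 in CD8 (59 at 0.05), and at 0.1 they numbered 66 in CD4 and 121 in CD8. The thresholds themselves account for these counts. The share of positive calls in CD4 went from 56.5% to 48.5% at 0.1, and in CD8 from 57.6% to 79.1% without pseudogenes, since the 16 pseudogenes left out were all negative. Of 72 named gene values, 23 were no longer past the threshold at 0.01. The Fisher list test passed 3 times, against 2 at 0.01 (the CD4 regulatory T cell list had an adjusted p of 0.0877), 8 with all listed genes (the CD4 Th1 list then had 0.0032) and 19 by the shift of all members at a correlation of 0.1. Both of the latter also change the number of lists tested, the last is a different test, and the cause was not tested. Neither the Fisher list test nor the binomial test on the signs of all CD8 calls was repeated without pseudogenes. Camera called 25 sets at a correlation of 0.01, 20 at 0.1, 24 on ranks at 0.01 and 13 on ranks at 0.1, and the cause of the last fall was not tested. The number of shared genes was 8 at 0.01, with the same sign in all, and 11 with a minimum log2 change of 1, without predicted genes and receptor segments, and without pseudogenes. The difference test called 10 genes with lower standard error bounds, 11 with 1.1 times as many tests and 8 with division by the robust SD.

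No paired analysis was possible because the tables hold the authors' fold changes and no values per library. For the same reason the settings on mean counts, tool, scaling, low-count filter, pseudocount and left-out replicates were not run. The unknown depth, the standard error bounds and 100 cells per library limit what a fold change near 0 shows: for a gene with the median bound, a 95% interval around 0 reaches a log2 change of 1.41 in CD4 and 1.29 in CD8, while genes with smaller bounds were called from 1.00 and 0.81.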

Other observations

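The tests in this part were chosen after the data had been seen, except for the counts of called members in lists fixed before the data were examined.

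In CD4 cells the proliferation list shifted to the negative side. All 11 listed proliferation genes were negative, with a median log2 fold change of −0.65 (camera, adjusted p = 0.0014, 0.0292 at a correlation of 0.1 and 0.0511 on ranks at that correlation), and Mcm6 was called. Of 13 glycolysis genes 10 were negative, with a median of −0.71 and 0 called (adjusted p = 0.0198, and 0.150 at a correlation of 0.1). In CD8 the same lists had medians of 0.12 over 9 genes and −0.13 over 11 genes, with adjusted p = 0.780 and 0.620, and their difference between the lineages had adjusted p = 0.131 and 0.395 at a correlation of 0.1. The 73 oxidative phosphorylation genes had 0 calls in either lineage (adjusted p = 0.943 in CD4 and 0.392 in CD8). The 15 mitochondrially encoded genes likewise had 0 calls (adjusted p = 0.209 and 0.339).

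In CD8, the shift of all members passed the test for several further lists. Apoptosis and survival genes had a median log2 fold change of 0.77 over 13 genes (adjusted p = 0.0180, and 0.118 at a correlation of 0.1), and T cell identity genes 0.20 over 33 genes (adjusted p = 0.0212, and 0.243 at a correlation of 0.1). The 4 listed Th17 genes had a median of 1.36 (adjusted p = 0.0097, and 0.0284 at a correlation of 0.1) with 0 called. The 3 gamma-delta and NKT cell markers had a median of 2.95 (adjusted p = 1.44e-04, and 6.38e-04 at a correlation of 0.1). The list has 22 genes, and the 2 called ones were the related constant genes Trgc2 and Trgc4. Immediate early genes had adjusted p = 4.63e-04, 0.0416 at a correlation of 0.1 and 0.170 on ranks at that correlation.

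The following lists did not pass the shift test at a correlation of 0.01. Interferon response genes had adjusted p = 0.168 in CD4 and 0.927 in CD8, with Ifi27l2a and Ly6a called in CD4 and Ly6e in CD8. Trafficking genes had 0.0802 and 0.0927, lectins 0.880 and 0.147, and the RNA quality list 0.214 and 0.147. In CD4, apoptosis genes had 0.566, T cell identity genes 0.894, Th17 genes 0.214, immediate early genes 0.448, naive and central memory genes 0.894, gamma-delta and NKT markers 0.462, and the 3 listed other glycan enzymes 0.0529. Regulatory T cell genes in CD8 had 0.0939 and follicular helper genes 0.927. Th2, plasma cell and dendritic cell lists had 2, 1 and 1 listed members, with 0 calls.

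For CD4 age-associated genes the tests differed in sign: the shift was positive on values (adjusted p = 2.01e-06, and 0.00301 at a correlation of 0.1) and negative on ranks (0.906), with a median of −0.13.

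All 2856 named genes of the CD8 table were also in the CD4 table. Cd8a was listed at exactly 0 in CD4, and Cd4 at exactly 0 in CD8. A candidate explanation is that the authors fitted 1 model over all 16 libraries and took both comparisons from it, which would keep genes that lack counts in a pair of groups. This is a hypothesis, as no source used here states the model. If so, both comparisons share a spread estimate and their standard errors are not fully independent.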
